A study of Mus musculus with 24 samples.

How the data were processed

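ATAC-seq libraries were made from 24 samples of the A2lox.cre mouse embryonic stem cell line, 2 biological replicates at each of 12 time points, from detergent-extracted nuclei tagged with a commercial transposase kit, per the labels' protocols. Adapter trimming, alignment, file handling and duplicate tools, and the peak caller, were cutadapt 2.10, Bowtie2 2.3.2, SAMtools 1.5, Picard and MACS2 2.1.1 with the mm10 build, per the submitters' processing notes. Those notes give the tools without their order or settings. How the 2 replicates of a time point were combined into 1 peak list, whether reads were shifted for the transposase offset, and the read depth are not given in the sources used here. The deposited data analysed here were 12 peak lists in the narrowPeak format. Signal tracks that the labels also name were not used here.

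Each deposited peak has an interval, a summit offset in base pairs, a fold enrichment, which is a linear ratio of signal to background, and the −log10 of a p-value and of a q-value, all as the authors' peak caller gave them. These values belong to single peaks of 1 list and were used only to describe, rank or filter peaks within a list. The smallest −log10 q was 1.30 to 1.31 in each list, so the lists share a q threshold near 0.05. All lists covered the 19 autosomes and chromosome X. Several summits can share an interval, with 1.12 per interval at 2i and 1.43 at D15, and each summit was counted as a peak. The median interval width was 471 bp at D4 and 651 bp at D15.

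Depth could not be read from the lists. The median −log10 p of peaks with a fold enrichment of 4.9 to 5.1 increases with background coverage. It was 7.69 at 2i, 8.75 at D0, 9.14 at D1, 8.65 at D2, 11.6 at D3 and 7.71 at D4. It was 8.62 at D5, 10.6 at D6, 9.64 at D7, 10.5 at D8, 11.1 at D10 and 11.5 at D15. Calls at 2i and D4 therefore had less statistical weight for the same enrichment. A region absent from a list is one not called there, not one shown to be closed. The weight was mostly higher in late lists, so trends with day cannot be separated from it. The same holds for the late-gained class below, which asks for absence from 2i and D0 and presence at D10 and D15.

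Peaks of all lists were merged with bedtools 2.31.1 into 128679 regions. A list held a region if any of its peaks overlapped it by at least 1 bp. Classes of regions were fixed before the data were examined: late-gained, early-lost, transient in at least 2 consecutive lists of D1 to D8, and the pair of classes for exit from 2i. Similarity of lists was the Jaccard index over regions. It was correlated with the difference in day by Spearman's rho over pairs of lists, with 100000 reassignments of days to whole lists (two-sided), since pairs of lists are not independent.

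Gene positions came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 names, with 21631 protein-coding genes on the chromosomes used and all 211 genes of the fixed groups matched by symbol. The table has gene bounds without strand, exons or transcript starts. The planned assignment to transcription start sites was therefore replaced by assignment to gene bodies. A summit or region centre was assigned to the gene whose body holds it, to the one with the nearest end if several do, and otherwise to the nearest gene body within 50 kb. Gene-end peaks are those with a summit within 1 kb of either annotated end, so they include transcript ends, and they can miss a promoter where the outermost annotated transcript starts elsewhere. Left and right of a gene are by coordinate, and exon or intron could not be given. A planned count of transcription factor motifs needs the genome sequence, which was not used here, and was not run.

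The 15 gene groups held 8 to 22 genes: naive pluripotency, formative and primed pluripotency, primitive streak and mesendoderm, early mesoderm, cardiac progenitor factors, sarcomere, cardiac calcium handling with ion channels and hormones, smooth muscle, endothelial, blood, epicardial and fibroblast, endoderm, neural ectoderm, skeletal muscle and housekeeping genes. The share of a list's peaks assigned to a group was correlated with day over 11 lists (2i has no day) by Spearman's rho and Pearson's r. Each had a two-sided permutation test with 100000 resamples and Benjamini-Hochberg adjustment over the 15 groups, with a threshold of 0.05. The number of class regions near a group was given as a percentile among 10000 random gene lists of the same size, matched on decile of the number of assigned regions. This is a description, with no p-value, and percentiles below 2.5 or above 97.5 are called outer. Shares have Wilson 95% intervals, which cover counting error only.

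Genes were named by a rule fixed before the data were examined. It took the up to 3 genes of each group with most regions of a class, the 5 genes with most genome-wide, and 32 marker genes in every case. Fewer are printed for some groups with few regions, and 1 gene of the genome-wide sets is not reported here. The region given by coordinates is the one of the class with the highest −log10 q in the last list that holds it. Coordinates are 1-based on mm10.

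The labels name 1 list for both replicates of a time point. From these lists no spread between replicates, no fit with a replicate left out and no test between 2 time points could be made. Alternatives were a −log10 q of at least 5, the same number of top peaks by −log10 p from each list (31324), a list covering at least 50% of a region, windows of 150 bp either side of summits, autosomes only, other end stages, assignment within 20 or 100 kb, gene-end windows of 500 bp and 2.5 kb, and lists left out. A further set was chosen after seeing the data: transient regions without the D7 or D4 list, trends without D1, D4 or D7, shares of assigned peaks only, 1 summit per interval, and distal peaks at equal number.

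The functions were tested on simulated data. All 5 region classes came back with the planted counts from 3200 simulated regions, and 1000 of 1000 random positions had the gene a direct search gave. The share of peaks against day was simulated with the real list sizes and 11 lists. Unadjusted p was under 0.05 in 5.5% of 200 simulated gene groups with no change, 88.5% with a 2-fold change over the days and 100% with a 4-fold change. These shares varied by counting error only, around a single base share. Real lists also differ in other ways, so the rates may be too favourable, above all for groups with few peaks. For the order of the lists in time, p was under 0.05 in 6% of 200 simulated sets with no order and in 100% with one. For the percentiles, 5.5% of 200 chance groups and 100% of 20 groups with a 3-fold share were outer. The simulated class held a larger share of regions than the late-gained class, which held 3.80%. The 100% may therefore be too favourable for groups with few class regions. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.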

Results

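Chromatin accessibility was profiled by ATAC-seq, which marks open DNA by inserting sequencing adapters with the Tn5 transposase, while A2lox.cre mouse embryonic stem cells differentiated towards cardiomyocytes. A2lox.cre is an established embryonic stem cell line that carries a docking site for inducible transgenes. The 24 samples comprised 2 biological replicates at each of 12 time points. The first was the 2i stage, a culture condition that holds stem cells in naive pluripotency. Days 0 to 8 (D0 to D8), D10 and D15 followed, in a course that the sample titles name mESC to CM (cardiomyocyte). How many cells were cardiomyocytes at D10 or D15 was not measured here. The labels name the same peak list for both replicates of a time point, so 12 peak lists were analysed and none of the values below has a replicate spread. Differences between 2 time points were therefore not tested, and the tests used the order of the time points. The lists held between 31324 peaks at D1 and 66993 at D7, with 46032 at 2i, 40370 at D0, 56053 at D4, 53633 at D8, 32641 at D10 and 36248 at D15. The ratio of the longest to the shortest list was 2.14. Sequencing depth was not given in the sources used here, so how far depth set these numbers is unknown.

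Merging all peaks gave 128679 regions on mm10, of which 11089 were open at all 12 time points and 56198 at 1 time point only. For regions, open means called in a list and closed means not called there. The regions open throughout lay mostly at genes: 76.4% (Wilson 95% interval 75.6 to 77.2%) were centred within 1 kb of an annotated end of a protein-coding gene, against 3.14% (3.00 to 3.29%) of those called at 1 time point. Intervals on shares cover counting error only. Among the fixed genes, Gapdh, a glycolytic enzyme used as a housekeeping control, had a peak at a gene end in all 12 lists. The same held for the developmental regulators Sox2, Klf4, Gata6, Hand2, Isl1 and Tbx20, whose ends were open from the 2i stage to D15.

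Whether cells closer in time shared more open chromatin was asked first. The Jaccard index, the number of shared regions over all regions of a pair of lists, fell with the difference in day over the 11 lists that have a day (Spearman's rho = -0.51 over pairs of lists, two-sided permutation p = 0.00212, 100000 reassignments of days to lists). Neighbouring lists were most alike from D7 to D8, with an index of 0.620, from D2 to D3 with 0.610, and from D10 to D15 with 0.598. They were least alike from D3 to D4, with 0.328, where 28231 regions were called at D4 and not at D3. The lowest index of all pairs was 0.224, between D1 and D7, the shortest and the longest list. With equal numbers of peaks that pair had 0.330 and the lowest was 0.314, between 2i and D15.

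**Figure D1:**
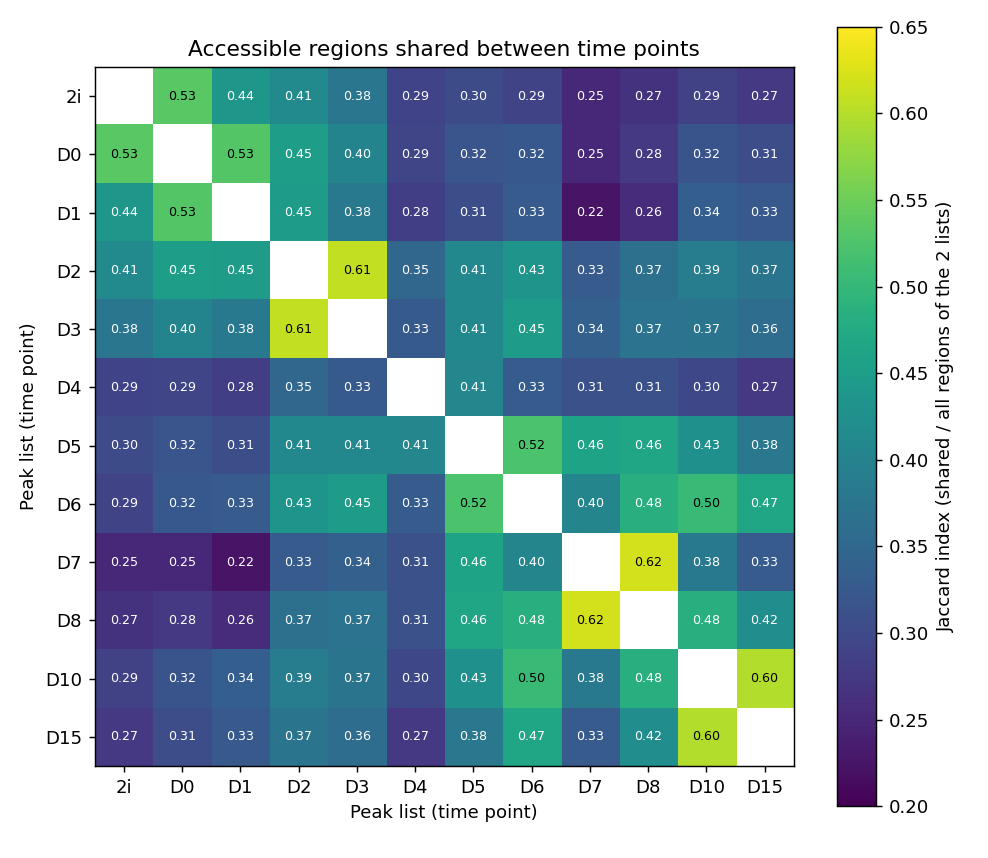
Jaccard index for each pair of the 12 peak lists, with the time points in order on both axes and the colour and number giving the index. The index reaches 0.620 for D7 and D8, but not every list is closest to its neighbours: D4 has 0.328 to D3 and 0.348 to D2.

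Regions gained late in the course were defined as open at both D10 and D15 and closed at both 2i and D0. There were 4885 such late-gained regions. They gathered at epicardial and fibroblast genes, and at genes for cardiac calcium handling, ion channels and hormones. The first group had 15 near 8 of its 13 genes and the second had 20 near 10 of its 17. Random gene lists matched on their number of regions gave medians of 4 and 9. The counts of 15 and 20 were at the 99.9th and 99.6th percentiles of 10000 random lists. Smooth muscle genes had 6 regions at 6 of 8 genes, against a random median of 1 (percentile 99.5). Naive pluripotency genes had none, against a median of 7 (percentile 0.085), as did primitive streak genes, against 3 (percentile 1.65), and neural ectoderm genes had 1, against 5 (percentile 1.70). With the same number of top peaks from each list, calcium and smooth muscle genes fell back to percentiles of 91.6 and 81.9 and neural genes moved to 3.27. Primitive streak genes moved to 2.61 and neural genes to 2.92 when regions were assigned within 20 kb.

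Single genes of these groups had at most 5 late-gained regions. Cacna1c, which encodes the pore of the L-type calcium channel, had 5. The one at chromosome 6, 119196237 to 119197051, lies inside the gene within 1 kb of its right end and was open from D4 onwards. Ryr2, the calcium release channel of the sarcoplasmic reticulum, had 4, with one 3.84 kb left of the gene (chromosome 13, 11548904 to 11549618) open at D7, D8, D10 and D15. The potassium channel gene Kcnq1 had 3. Of the epicardial and fibroblast genes, Wt1, an epicardial transcription factor, had 3 and the collagen genes Col1a1 and Col1a2 had 2 each. The Col1a2 region at chromosome 6, 4489192 to 4490451, lies 15.8 kb left of the gene and was open from D4 onwards. Of the 20 cardiac progenitor factors 9 had a late-gained region, 16 in all (percentile 88.5). Gata4, a core cardiac transcription factor, and Meis1 had 3 each and Gata5 had 2. One Gata4 region, at chromosome 14, 63271402 to 63272119, lies at 1 end of the gene and was open from D7. Sarcomere genes had 10 regions at 8 of 22 genes (percentile 92.6), with 2 each at Nebl and Tnni1 and 1 at Csrp3. The smooth muscle genes Acta2, Cnn1 and Lmod1 had 1 each.

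The other gene groups were within the middle 95% of random lists for late-gained regions. Formative and primed pluripotency genes had 9 (percentile 92.0), 5 of them at Dnmt3a, a DNA methyltransferase, and 1 each at Dnmt3b and Fgf5. Endothelial genes had 7 (percentile 66.6), with 2 each at Emcn and Flt1 and 1 at Cdh5. Early mesoderm genes had 5 (percentile 61.4), including 1 each at Aplnr, Bmp4 and Kdr. Blood genes had 2 (percentile 45.1), at Gata2 and Tal1, and housekeeping genes 2 (percentile 49.8), both at Actb. Endoderm and skeletal muscle genes had 0 (percentiles 3.02 and 11.5), and endoderm genes were at the 1.55 percentile within 100 kb. The single neural region was at Nes. Genome-wide the genes with most late-gained regions were Nav2 with 8 and Itpr1, Kalrn, Lrmda and Maml3 with 6 each, all of them long, from 338 kb for Itpr1 to 1036.59 kb for Lrmda. The Maml3 region at chromosome 3, 51915641 to 51916653, inside the gene, had a fold enrichment of 10.8 at D15 by the authors' own peak value.

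Late-gained regions were called in part before D10. Of the 4885, 4.95% were already called at D1, 21.1% at D2, 44.3% at D5, 45.4% at D6, 78.3% at D7 and 83.9% at D8. The step from D6 to D7 goes with the length of the lists, 32791 and 66993 peaks. Their centres were inside a gene body for 52.8% (51.4 to 54.2%), within 1 kb of a gene end for 10.5% (9.63 to 11.4%) and over 50 kb from any protein-coding gene for 20% (18.9 to 21.1%). The count depended on the definition: it was 3027 among peaks with a −log10 q of at least 5, 9918 with D15 alone and 10084 with D10 alone as the late stage.

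**Figure D2:**
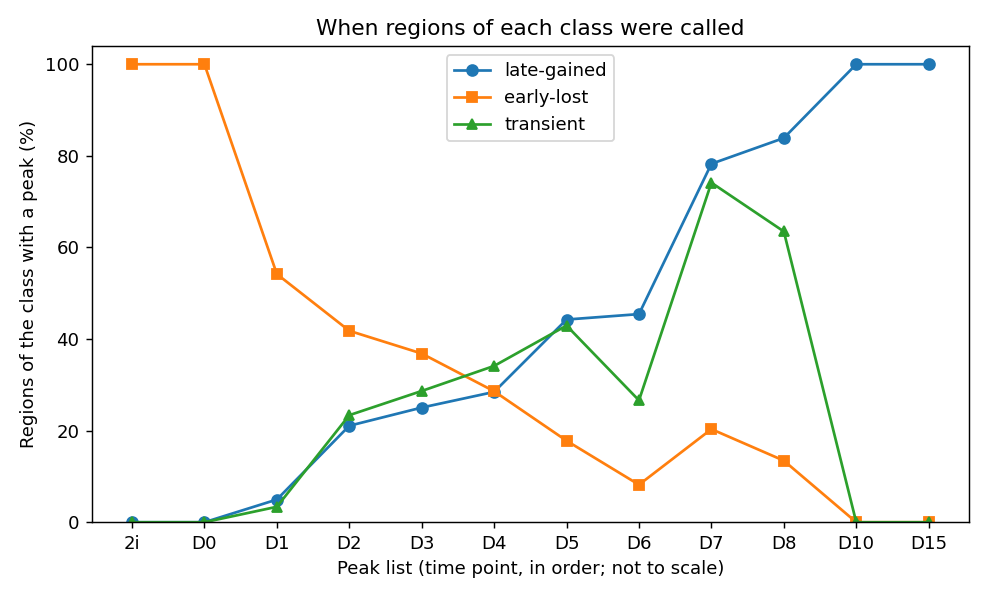
Percent of the late-gained, early-lost and transient regions with a peak in each of the 12 lists, in order of time on an axis not drawn to scale. Late-gained regions pass from 4.95% at D1 to 83.9% at D8. Early-lost regions pass from 54.2% at D1 to 8.19% at D6 and are at 20.3% at D7. By definition each class is at 0 or 100% in the lists that define it.

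Regions lost on differentiation, open at both 2i and D0 and closed at both D10 and D15, numbered 12297. Naive pluripotency genes stood apart: 38 early-lost regions lay near 15 of the 17 genes, against a random median of 15 (percentile 99.96), and they remained above the 99th percentile within 20 kb, within 100 kb and with equal numbers of peaks. Esrrb, a nuclear receptor of the naive network, had 6, including chromosome 12, 86469936 to 86471525, inside the gene and open from 2i to D3. Zfp42, which encodes the stem cell marker Rex1, had 5, including chromosome 8, 43320687 to 43321563, 14.1 kb right of the gene and open at 2i, D0 and D1. Dppa3 and Tfcp2l1 had 3 each, Sox2 had 2, and Klf4 and Pou5f1 had 1 each, while Nanog had 0.

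None of the other groups was outside the middle 95% for early-lost regions. Cardiac calcium and ion channel genes had 25 (percentile 86.1), with 6 at Trdn, 5 at the connexin gene Gja1 and 4 at Ryr2. Neural ectoderm genes had 19 (percentile 93.0), with 4 at Pax6, 3 at Sox1 and 2 at En1. Cardiac progenitor factors had 17 (percentile 15.8), including 4 at Meis2 and 3 at Fgf10, and this group fell to the 2.03 percentile with equal numbers of peaks. Formative genes had 13 (percentile 72.2), with 4 at Foxd3, 3 at Otx2 and 2 at Lef1, and endothelial genes had 11 (percentile 44.1), with 3 at Cdh5. Primitive streak genes had 6 (percentile 30.4), among them 1 each at Eomes, Gsc and Lhx1. Endoderm genes had 6 (percentile 45.8), 3 of them at Foxa1. Sarcomere genes also had 6 (percentile 4.84), 3 of them at Nebl. Early mesoderm genes had 5 (percentile 10.9), 3 of them at Bmp4, and epicardial and fibroblast genes had 5 (percentile 8.80), 2 of them at Fn1. Housekeeping genes had 4 (percentile 46.5), blood genes 1, at Spi1 (percentile 3.13), smooth muscle genes 1, at Acta2 (percentile 11.7), and skeletal muscle genes 0 (percentile 2.54, and 2.32 within 100 kb).

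Early-lost regions lay far from genes more often than late-gained ones. Of the early-lost regions 32.0% (31.2 to 32.9%) were over 50 kb from a protein-coding gene and 4.89% (4.52 to 5.28%) were within 1 kb of a gene end. The genes with most were very long: Macrod2 and Pde4d with 18, Immp2l with 15, and Magi2 with 12, at lengths of 931.528 to 1997.66 kb. Early-lost regions were called less often over time, with 54.2% at D1, 36.8% at D3 and 17.8% at D5. The share was 8.19% at D6, a list of 32791 peaks, then 20.3% at D7, the longest list, and 13.5% at D8. The count was 6353 with a −log10 q of at least 5 and 7893 with equal numbers of peaks. It was 25210 with 2i alone and 19515 with D0 alone as the early stage.

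Regions open only in between, in at least 2 consecutive lists of D1 to D8 and in none of 2i, D0, D10 and D15, numbered 18953. They gathered at primitive streak and mesendoderm genes, with 30 regions at 12 of 13 genes against a random median of 14 (percentile 99.7), and at cardiac progenitor factors, with 70 at 19 of 20 genes against 44 (percentile 99.4). Smooth muscle genes had 12 at 7 of 8 genes against 5 (percentile 99.3) and skeletal muscle genes 14 at 5 of 10 genes against 6 (percentile 97.8). With equal numbers of peaks the cardiac progenitor factors were at the 92.5th percentile, with 31 regions. Skeletal muscle genes were at the 94.7th percentile within 20 kb and at the 97.4th within 100 kb.

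Tbx5, a transcription factor of the first heart field, had the most transient regions of the progenitor factors, 9, including chromosome 5, 119874707 to 119876002, inside the gene and open at D3 and from D5 to D8. Meis2 had 7, Gata4 had 6, Mef2c had 5, and Nkx2-5 and Isl1 had 3 each. Of the streak genes, Lhx1 had 5 and Fgf8 and Gsc had 4 each. A Fgf8 region 2.94 kb left of the gene (chromosome 19, 45733229 to 45733865) was open from D3 to D6. Skeletal muscle regions were concentrated at Pax7, a factor of muscle and neural crest precursors, with 8, including chromosome 4, 139843361 to 139843968, 10.1 kb right of the gene and open at D2 and D3. Myh3 and Myod1 had 2 each. Of the smooth muscle genes Myh11 had 3 and Cnn1 and Lmod1 had 2 each.

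Early mesoderm genes had 28 transient regions (percentile 95.2), which passed to the 98.9th percentile with equal numbers of peaks and the 98.8th within 100 kb. Kdr, the VEGF receptor of early mesoderm and endothelium, had 7, and Bmp4 and Snai1 had 4 each. The remaining groups were within the middle 95%. Cardiac calcium and ion channel genes had 38 (percentile 64.5), with 7 each at Cacna1c and Ryr2, and neural genes had 28 (percentile 83.4), with 4 at Pax3. Sarcomere genes had 24 (percentile 61.2), with 3 each at Ldb3 and Tnni1. Formative genes had 23 (percentile 72.0), with 6 at Pou3f1, and endothelial genes also had 23 (percentile 51.4), with 7 at Flt1 and 5 at Fli1. Naive genes had 20 (percentile 8.76), with 5 at Tbx3, and epicardial and fibroblast genes 13 (percentile 17.3), with 3 each at Col1a2 and Dcn. Endoderm genes had 12 (percentile 58.1), blood genes 9 (percentile 50.1), 5 of them at Runx1, and housekeeping genes 4 (percentile 10.0). Genome-wide, Msi2 had 20 and Sdk1 19, and Gse1, Nav2 and Trabd2b had 18 each. The count of transient regions rested on the D7 list, without which it was 11261. It was 8887 with equal numbers of peaks and 5231 when 3 consecutive lists were required. Over these 3 classes and 15 gene groups, 11 of 45 percentiles lay in the outer 5%, where 2.25 would by chance.

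The share of each list's peaks that lay near a gene group was then set against day, over the 11 lists with a day and 15 gene groups fixed before the data were examined. Peaks near naive pluripotency genes fell, from 1.78 per 1000 peaks at D0 (Wilson 95% interval 1.42 to 2.25) to 0.635 at D15 (0.423 to 0.952). Spearman's rho was -0.87 (permutation p = 0.00094, adjusted p = 0.00705) and Pearson's r was -0.82 (permutation p = 0.00133, adjusted p = 0.00997). Leaving out the lists farthest from the median day gave r = -0.75 without D15 and D10 and r = -0.73 without D15 and D0. Peaks near epicardial and fibroblast genes rose, from 0.471 per 1000 at D0 (0.301 to 0.735) to 1.24 at D15 (0.928 to 1.66). Spearman's rho was 0.98, with a permutation p of 1e-05, the smallest that 100000 resamples can give, and an adjusted p of 0.00015. Pearson's r was 0.92 (permutation p = 2e-05, adjusted p = 0.0003), and it was 0.98 without D15 and D10 and 0.96 without D15 and D0. The naive trend missed the threshold without D15 and D0 (rho = -0.82, permutation test, adjusted p = 0.0805) and among gene-end peaks only (rho = -0.77, adjusted p = 0.0555). The epicardial and fibroblast trend missed it among peaks with a −log10 q of at least 5 (rho = 0.75, permutation test, adjusted p = 0.085).

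Peaks near genes of cardiac calcium handling, ion channels and hormones rose by rank, from 1.34 per 1000 at D0 (1.03 to 1.74) to 2.14 at D8 (1.79 to 2.57) and 1.74 at D15 (1.36 to 2.22). Spearman's rho was 0.78 (permutation p = 0.00651, adjusted p = 0.0325), but Pearson's r of 0.63 did not pass (permutation p = 0.0343, adjusted p = 0.15). Peaks near smooth muscle genes also rose by rank, with rho = 0.74 (permutation p = 0.0129, adjusted p = 0.0485). Their share was 0.149 per 1000 at D0 (0.0681 to 0.324), highest at D6 with 0.518 (0.324 to 0.830), and 0.386 at D15 (0.230 to 0.648). Their r of 0.62 did not pass either (permutation p = 0.0401, adjusted p = 0.15). Without D15 and D10 the r values were 0.88 and 0.84, and without D15 and D0 they were 0.84 and 0.66. Both rank trends missed the threshold with equal numbers of peaks (rho = 0.64 and permutation test, adjusted p = 0.094 for each) and with a −log10 q of at least 5 (rho = 0.66 and 0.59, adjusted p = 0.158 and 0.164). The same held without D15 and D0 (rho = 0.77 and 0.68, permutation tests, adjusted p = 0.106 and 0.143) and among gene-end peaks only (rho = 0.66 and 0.57, adjusted p = 0.114 and 0.152). They also missed it without the D1 list (rho = 0.76 and 0.66, permutation tests, adjusted p = 0.0741 and 0.162), where 10 lists remained. Without the D4 list they missed it as well (rho = 0.78 and 0.68, permutation tests, adjusted p = 0.0522 and 0.132). In all, the calcium trend missed it in 6 alternative settings and the smooth muscle trend in 7.

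**Figure D3:**
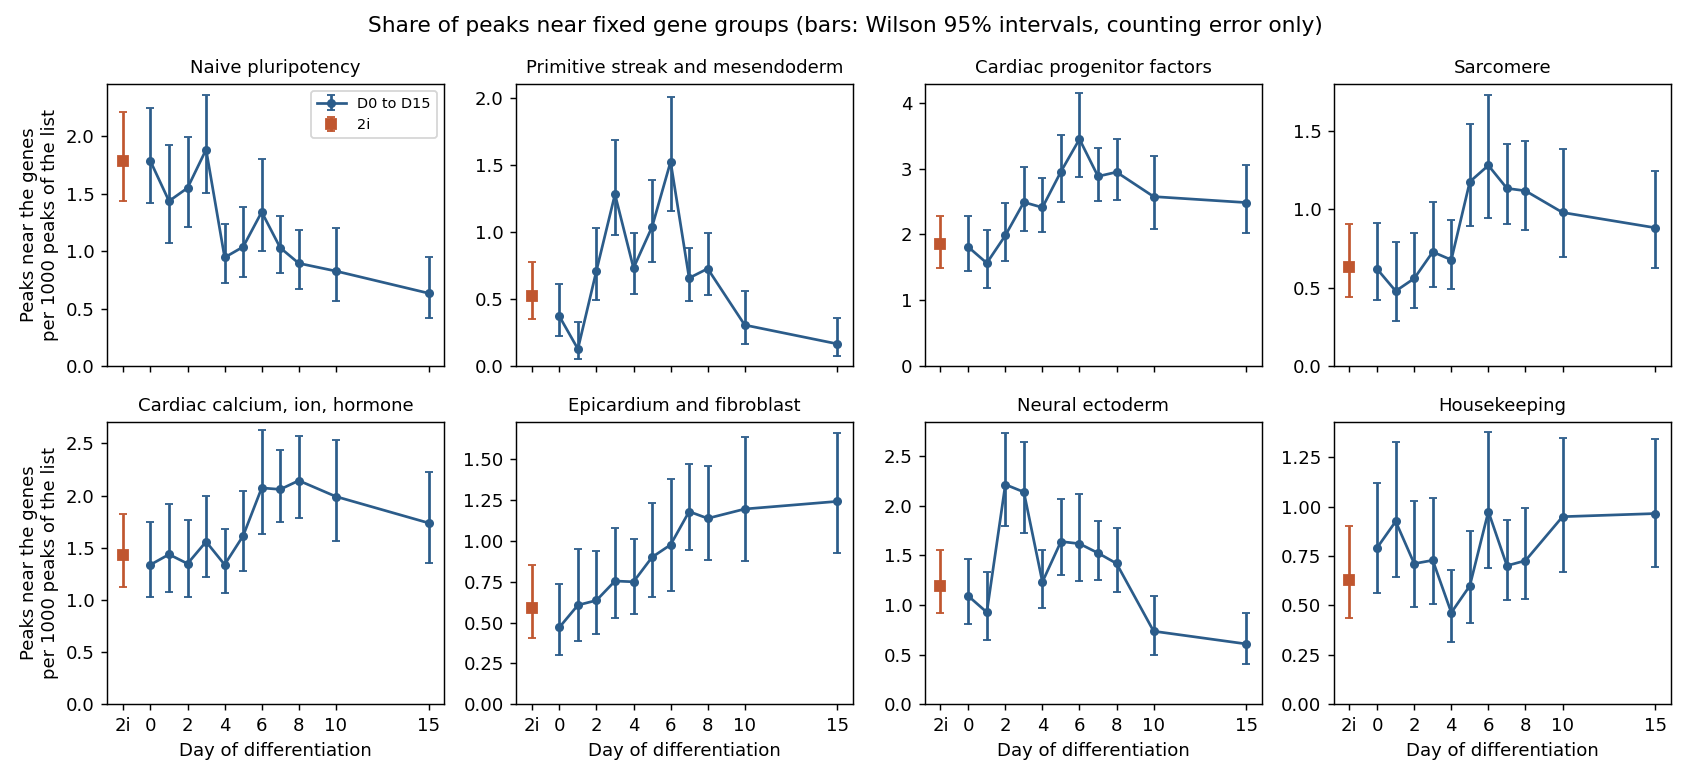
Peaks near 8 of the fixed gene groups per 1000 peaks of each list against day, with 2i as a separate square at the left and bars giving Wilson 95% intervals for counting error only. The naive pluripotency share passes from 1.78 at D0 to 0.635 at D15 and the epicardial and fibroblast share from 0.471 to 1.24, while cardiac progenitor and sarcomere shares are highest at D6, at 3.45 and 1.28.

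The genes that define the cardiac fate did not follow day in a straight course. The share near cardiac progenitor factors was 1.56 per 1000 at D1 (1.18 to 2.07), 3.45 at D6 (2.87 to 4.14) and 2.48 at D15 (2.02 to 3.05). Its rank trend did not pass (rho = 0.62, permutation p = 0.048, adjusted p = 0.12, with r = 0.50, permutation p = 0.118, adjusted p = 0.253). The sarcomere share was 0.479 per 1000 at D1 (0.290 to 0.790), 1.28 at D6 (0.948 to 1.73) and 0.883 at D15 (0.625 to 1.25), with rho = 0.65 (permutation p = 0.0336, adjusted p = 0.101) and r = 0.54 (permutation p = 0.0846, adjusted p = 0.253). The progenitor trend passed among gene-distal peaks (rho = 0.76, permutation test, adjusted p = 0.0339) and with 1 summit per interval (rho = 0.73, adjusted p = 0.0439). Both trends passed over 12 lists with 2i placed before D0 (permutation tests, adjusted p = 0.0422 for each). Without D15 and D10 both passed by rank, with permutation tests giving adjusted p = 0.0316 for the progenitor factors and 0.0376 for the sarcomere, and 8 of the 15 groups passed. Primitive streak genes took 0.128 per 1000 peaks at D1 (0.0497 to 0.328), 1.52 at D6 (1.16 to 2.01) and 0.166 at D15 (0.0759 to 0.361), with rho = -0.05 (permutation p = 0.883).

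In all, 4 of the 15 groups passed by Spearman's rho and 2 by Pearson's r. The other groups had rho of 0.50 for early mesoderm (permutation test, adjusted p = 0.26), 0.37 for endothelial and 0.36 for blood genes (adjusted p = 0.455 for each). Early mesoderm, endothelial and blood genes each passed in 1 alternative setting. By the same test rho was 0.24 for housekeeping (adjusted p = 0.605) and 0.11 for formative genes (0.808). Spearman's rho was -0.34 for neural ectoderm (permutation test, adjusted p = 0.47), -0.30 for endoderm (0.508) and -0.15 for skeletal muscle (0.778). The r values of these groups and of the streak genes were between -0.50 for endoderm and 0.42 for early mesoderm, with permutation tests giving adjusted p from 0.253 to 0.631.

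Peaks at the marker genes are given as counts per list without a test, and not every gene followed its group. Pou5f1, the core pluripotency factor Oct4, had 3 peaks at 2i, 1 to 2 from D0 to D4 and 0 from D5 onwards, and a peak at a gene end at 2i, D1, D2 and D3. Esrrb had 11 at 2i, 14 at D3, 1 at D10 and 0 at D15. Tfcp2l1 had 8 at 2i and 1 at D15. Otx2, a formative factor, had 9 at D3 and 0 at D15. Nanog did not empty, with 3 at 2i and 5 at D15, though its gene-end peak was last called at D6. T (brachyury), which marks the primitive streak, had assigned peaks only from D2 to D8, with 3 at D7, and a peak at a gene end at D0 and from D2 to D8. Mixl1 had 1 or 2 up to D8 and 0 at D10 and D15. Eomes, a mesendoderm regulator, had 1 at D1, 9 at D4 and D5 and 1 at D10. Mesp1, which marks the earliest cardiac mesoderm, had 0 at D0 and D1, 5 at D5 and 1 at D10 and at D15. Kdr had 2 at D1 and 10 at D7, and Pdgfra had 1 at D1 and 8 at D7.

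Gata4 had 2 peaks at 2i, 14 at D8 and 11 at D15, with a gene-end peak only from D7 onwards. Gata6 had 1 at 2i, 10 at D7 and D8 and 5 at D15. Hand2, a regulator of the second heart field, had 7 at 2i and 12 at D15. Isl1 had 10 at D4 and 2 at D15. Nkx2-5 had 0 at 2i, 5 at D3, 0 at D4 and 5 at D6 and D7. Tbx5 had 0 up to D1, 16 at D7 and 13 at D8, then 0 at D10 and 1 at D15. Tbx20 had 4 at 2i and 1 at D15, and Mef2c had 10 and 7. Of the contractile genes, cardiac troponin T (Tnnt2) had a gene-end peak in every list from D5 to D15 and in none before, and cardiac actin (Actc1) had one from D5 to D8. Myl7 had 0 peaks from D0 to D3, 4 at D5 and 3 at D15. The myosin heavy chain genes Myh6 and Myh7 had at most 1 and 3 peaks in any list, titin (Ttn) had 5 at D4 and 0 at D10 and D15, and the natriuretic peptide gene Nppa had 1 at D5 and at D7 and 0 elsewhere. Ryr2 had 11 at 2i and 16 at D7. The housekeeping genes Actb and Gapdh had 3 to 8 and 1 to 5 peaks. Actb had no summit within 1 kb of its outermost annotated ends in any list. Those ends can lie beyond the promoter in use, but this was not tested for Actb. The number of peaks per gene also moves with the length of the list, which was greatest at D7.

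**Figure D4:**
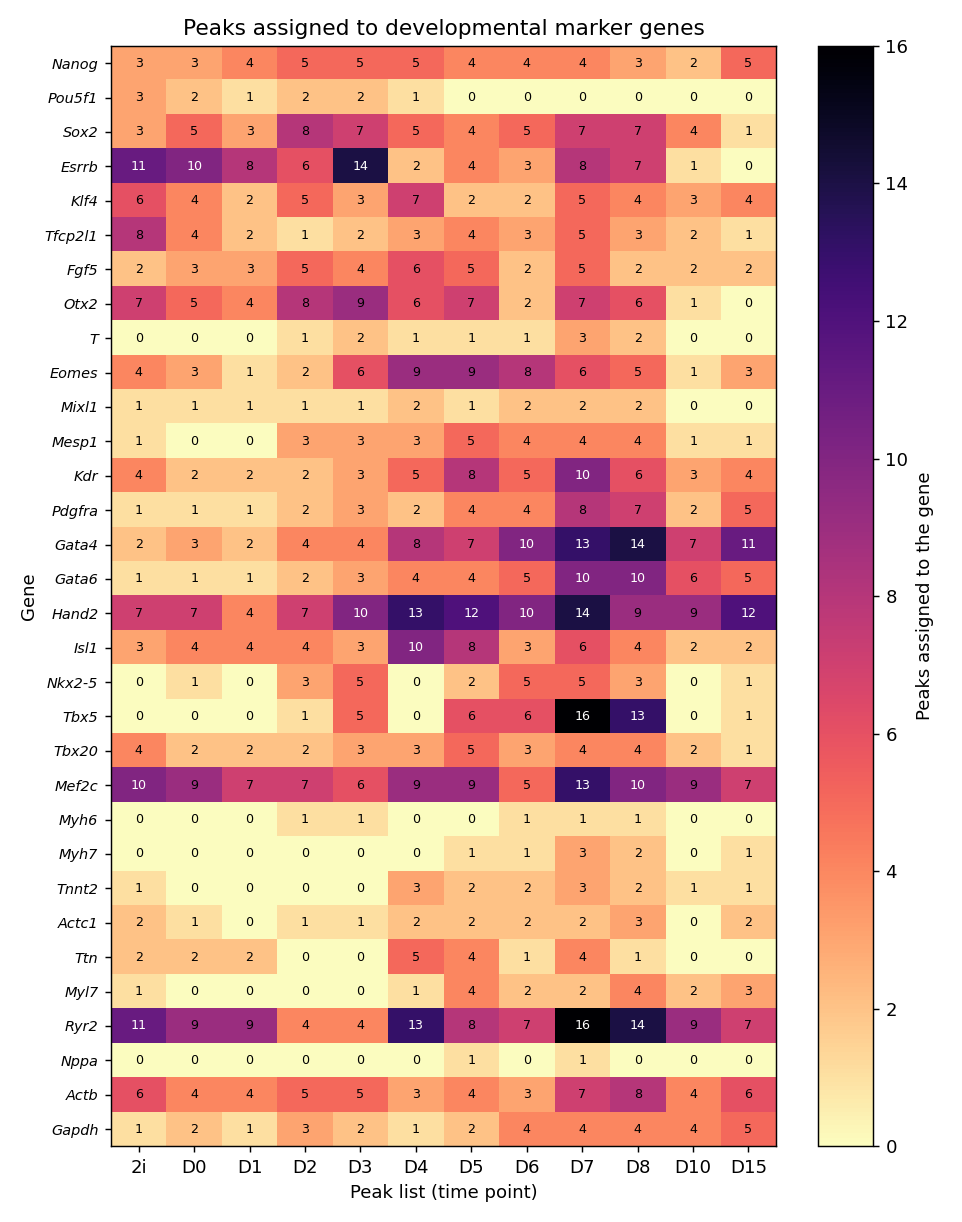
Number of peaks assigned to each of 32 marker genes (rows) in each of the 12 lists (columns), with the colour and the number giving the count. Tbx5 has 16 peaks at D7 and 13 at D8 but 0 at D10, Gata4 keeps 11 at D15, and Pou5f1 has 0 from D5 onwards.

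Exit from the 2i stage was described by 2 classes. Regions open at 2i and closed at D0 and D1 numbered 13004, and regions closed at 2i and open at D0 and D1 numbered 2191. Near naive genes 21 regions closed on exit (percentile 68.9), with 4 each at Esrrb and Zfp42 and 2 at Dppa3, and 4 opened (percentile 87.9), with 2 at Esrrb and 1 each at Nanog and Sall4. The Nanog region, at chromosome 6, 122713032 to 122713597, lies inside the gene and was called at D0 and D1 only. Near formative genes 8 closed (percentile 11), including 3 at Zic5 and 2 at Otx2, and 1 opened (percentile 42.9), at Dnmt3a. Near cardiac progenitor factors 22 closed (percentile 19.6), with 5 at Meis2, 4 at Zfpm2 and 3 at Mef2c, and 4 opened (percentile 72.3). None of the 30 percentiles of these classes lay in the outer 5%. With equal numbers of peaks, regions opening near naive genes, 8 in number, moved to the 98.8th percentile and regions closing near formative genes to 1.48. Within 20 kb regions closing near smooth muscle genes moved to 1.74. The genes with most closing regions were Auts2 with 25, Pard3 with 23, Slc39a11 with 18, Tenm4 with 17 and Pde4d with 14. Those with most opening regions were Dlg2 with 5 and Lrrtm4, Nkain3, Ptprd and Sgcz with 4 each. Of the regions that opened, 42.3% (40.3 to 44.4%) were over 50 kb from a gene, against 23.7% (23.0 to 24.4%) of those that closed. The whole lists differed in the same direction, though by less, with 18.7% of peaks that far from genes at 2i, 20.2% at D0 and 22.1% at D1. A difference between the lists stays open, and calls at 2i had less statistical weight. The closing count was 8174 with a −log10 q of at least 5 and 6570 with equal numbers of peaks, and the opening count was 1254 with the stricter q and 3073 with equal numbers of peaks. The classes are not mirror images, since closing asks for absence from 2 lists and opening for presence in 2.

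The share of peaks at gene ends showed no trend with day over all peaks. It was 29.2% at 2i, 34.6% at D0, 24.9% at D7, 45.3% at D10 and 48.7% at D15, with rho = 0.22 (permutation p = 0.521) and r = 0.39 (permutation p = 0.24). Without D15 and D10 r was -0.43 (permutation p = 0.244), and without D15 and D0 it was -0.02 (permutation p = 0.963). The longest lists, D7, D4, D8 and 2i, had the lowest shares, with 27.3% at D4 and 30.4% at D8, so list length can hide a trend. With equal numbers of peaks from each list rho was 0.65 (permutation p = 0.037).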

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

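The order of the lists in time kept its direction and its side of the threshold under all 6 other settings and with each of the 11 lists left out, with rho from -0.37 (−log10 q of at least 5, permutation p = 0.0202) to -0.73 (12 lists by rank, permutation p = 1e-05, the smallest possible). The class counts were less fixed. With a −log10 q of at least 5 they were 3027 late-gained, 6353 early-lost, 8174 closing and 1254 opening on exit from 2i. With equal numbers of peaks they were 7893 early-lost, 8887 transient and 6570 closing on exit, while late-gained regions were 4773 and opening ones 3073. That setting cut the 2i list from 46032 to 31324 peaks and left D1 whole. More regions could therefore count as absent from 2i, which raises the opening count. The cause of the other changes was not tested. Late-gained regions were 9918 with D15 alone and 10084 with D10 alone, early-lost 25210 with 2i alone and 19515 with D0 alone, since asking for 1 list in place of a pair admits more. Transient regions were 5231 with 3 consecutive lists and, in a setting added after seeing the data, 11261 without D7. Of the 15 gene groups, 4 followed day by rank, against 2 with equal numbers of peaks, 1 with the stricter q, 8 without D15 and D10, 1 without D15 and D0, 1 among gene-end peaks, and, added after seeing the data, 2 without D1 and 2 without D4. The cause was not tested here either. Over the groups, 200 of 225 alternative trends kept their side of the threshold, 16 lost it and 9 gained it. Most of the 200 belong to groups that did not pass in the main setting. All 16 losses were in the 4 groups that did: 7 for smooth muscle, 6 for calcium, 2 for naive and 1 for epicardial and fibroblast genes. The smooth muscle trend kept its call in 8 alternatives and the calcium trend in 9. The sign of rho changed only for groups that passed in neither setting. The share of peaks at gene ends passed only with equal numbers of peaks (rho = 0.645, permutation p = 0.037). No paired analysis was possible with the peak lists, because the labels name 1 list for both replicates of a time point. For the same reason no replicate could be left out of them. The motif alternatives were not run, as the motif count itself was not. Unknown depth limits each statement that a region is absent.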

Other observations

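The tests of the D4 list on stricter and on equal numbers of peaks, and the windows of neighbouring lists, were chosen after the results were seen. Peaks near neural ectoderm genes made up 0.926 per 1000 at D1 (Wilson 95% interval 0.645 to 1.33), 2.21 at D2 (1.79 to 2.73), 2.14 at D3 (1.73 to 2.64) and 1.23 at D4 (0.973 to 1.56). From D5 to D8 the neural share was 1.64, 1.62, 1.52 and 1.42. Sox1, an early neural factor, had 5 peaks at D1, 13 at D2, 10 at D3, 4 at D4 and 14 at D7. Pax7 had 0 at D1, 10 at D2, 11 at D3 and 2 at D4, then 7, 9, 8 and 6 from D5 to D8. Skeletal muscle genes took 0.192 per 1000 at D1 (0.0878 to 0.418), 0.628 at D3 (0.426 to 0.928) and 0.161 at D4 (0.0845 to 0.305). Their share was 0.346 at D5, 0.457 at D6, 0.313 at D7 and 0.317 at D8. In both groups the lower share at D4 was not kept in the lists from D5 to D8. In all, 4712 regions were open at D2 and D3 and closed at D1 and D4. Of these, 13 lay near neural genes (percentile 98.5 of random lists), at 9 of the 16 genes including Pax6, Pax3, Lhx2 and Six3 with 2 each, and 6 near skeletal muscle genes (percentile 98.5), 4 of them at Pax7. Over 60 such percentiles 4 were outer, where chance gives 3, so neither stands out as a group.

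The mean Jaccard index of the D4 list with D3 and with D5 fell short of that between D3 and D5 by 0.0421 (95% interval 0.0356 to 0.0489, from resampled chromosomes), through the pair of D3 and D4 with 0.328, while D4 and D5 had 0.408 and D3 and D5 0.410. Weak calls, unequal list lengths and calls far from genes may each account for part, since the shortfall was 0.0252 (0.0171 to 0.0349) with a −log10 q of at least 5, 0.0223 (0.0143 to 0.0316) with equal numbers of peaks and 0.0247 (0.0168 to 0.0326) within 50 kb of genes, against -0.00598 (-0.0117 to -0.000908) beyond 50 kb. Each of the 3 settings, taken alone, left a shortfall above 0. They were not combined, so whether they account for it together is unknown. A cut on −log10 q also does not even out the lower statistical weight of calls at D4. Resampled chromosomes carry no spread between libraries. A chromatin state of day 4 at streak or early mesoderm genes stays open: regions at D4 and at neither neighbour were at the 11.1 and 2.29 percentiles there, but none of the 15 groups was above 45.3 and 43.2% of these regions were over 50 kb from a gene, so the test decides nothing. The quality of the D4 libraries stays open as well.

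Peaks near cardiac progenitor factors numbered 174 in D10 and D15 against 351 in D7 and D8. As shares the ratio was 0.868 (0.724 to 1.04). The lists held 68889 peaks in D10 and D15 against 120626 in D7 and D8, so much of the gap in number goes with list length. Shorter lists or fewer distal peaks may also bear on the ratio of shares. It was 0.910 (0.731 to 1.13) with equal numbers of peaks and 0.979 (0.792 to 1.21) among gene-distal peaks. A larger share of epicardial or fibroblast cells, a hypothesis from 13 marker genes, gave a ratio of 1.18 (0.833 to 1.66) for their share of distal peaks, but 0.892 (0.580 to 1.37) for distal peaks and 0.920 (0.664 to 1.28) for all peaks at equal numbers. Each interval includes 1, so a fall in share was not shown. Beyond list length, these explanations cannot be told apart at this number of peaks.

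Early-lost regions lay over 50 kb from genes more often than late-gained ones. Weak calls at 2i and D0 alone are unlikely to be the cause. With a −log10 q of at least 5 the shares were 32.9% and 16.8%, a difference of 16.1 percentage points. That cut applied to all lists, so it also changed which regions count as absent. The whole lists differ in the same direction, with 18.7% of peaks that far from genes at 2i and 20.2% at D0. At D10 it was 10.3% and at D15 8.48%, so a difference between the lists stays open. No biological explanation was tested.

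Regions open at D1 and D4 and closed at D2 and D3 numbered 1452, and 48.8% of them were over 50 kb from a gene. The lists with the largest shares of peaks that far from genes were D4 with 24.8%, D1 with 22.1%, D0 with 20.2% and 2i with 18.7%, against 8.48% at D15. Open regions at both 2i and D10 and closed at D0 and D15, a pattern that runs against the order of time, numbered 433.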
